A study of Mus musculus with 10 samples.

How the data were processed

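Gene expression was measured by RNA-seq of total RNA from 10 sorted samples of C57BL/6 mice, 5 of GMP (3 KO, 2 CTRL) and 5 of LSK (3 KO, 2 CTRL). Per the labels' protocols, Cre was induced by 5 injections of poly(I:C), cells were sorted after depletion of lineage-positive cells, and libraries were made with a stranded total RNA kit that removes ribosomal RNA. Such libraries also hold unspliced RNA and RNA without a poly(A) tail. Samples were grouped by genotype and cell type as their titles give them. The description of GMP sample KO-352 refers to LSK data, in conflict with its title, which was followed. On the first principal component of all 10 libraries KO-352 lay at −133, within the range of the GMP libraries (−139 to −99.2). The LSK libraries lay at 117 to 119. The numbers in the titles are not shared between groups and pair no samples, and apart from these numbers nothing in the labels used here says that each library is a separate animal; p-values measure the spread between these libraries.

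The deposited raw tables hold counts of reads per Ensembl gene, made by the authors with STAR, HTSeq 0.5.3p3, DESeq 1.18.0 and DESeq2 1.4.5 on mm10 (GRCm38), per the submitters' processing notes, which give neither roles nor order; the annotation release and the strand setting of the counting are not given in the sources used here. The raw counts cover 38924 genes in GMP and 45513 in LSK, so the tables were counted on different annotations, and 38086 gene IDs are in both. Symbols were found for 37607 GMP and 44585 LSK gene IDs in GENCODE, whose build is also GRCm38, and coordinates are from that annotation, 1-based. The GMP table ends in lines of totals that name no gene, which were left out of library sizes and tests: reads outside annotated genes made 15.5%, 16.1%, 8.5%, 14.2% and 10.3% of all reads listed in KO-178, KO-179, CTRL-346, CTRL-350 and KO-352, reads aligned to several places 26.3% to 29.0%, and ambiguous reads 1.1% to 1.3%. Reads aligned to several places were not counted on genes, which lowers the counts of genes with near-identical copies. The deposited normalized tables hold a signal that equals the raw counts divided by 1 size factor per library, within 0.1% for at least 99.92% of the genes compared, and they were used to recover those size factors as an alternative scaling.

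Total gene counts were 101718692, 122658636, 100433192, 93850256 and 99328052 in GMP KO-178, KO-179, CTRL-346, CTRL-350 and KO-352, and 30028937, 30437981, 29817790, 29533371 and 30166772 in LSK CTRL-1326, KO-1327, CTRL-1330, KO-1333 and KO-1334. Where a group had 0 reads the fold was set against a floor of 3 counts over that group, and with 1 to 3 reads a 95% exact interval of the ratio of counts was used. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. No 2 libraries agreed within sampling noise.

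Counts were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr with its minimum count of 10, TMM normalization, the quasi-likelihood test (glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. GMP and LSK were fitted separately, with 3 residual degrees of freedom each. The difference of KO effects between populations (LSK minus GMP), their mean, and LSK against GMP in CTRL came from a fit of all 10 libraries with 1 mean per group over the gene IDs in both tables. SE is the size of the fitted log2 fold change divided by the square root of the F statistic of its test. It was not estimated apart from that test, and for genes near 0 in a group it should not be read as counting error. CPM uses the TMM library sizes of the population. A total of 25 gene lists, fixed before the data were examined, were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which asks whether a list moves on balance and does not compare it with other genes; 24 lists could be tested in LSK. With an estimated correlation 0 lists passed in GMP (lowest adjusted p = 0.56) and 0 in LSK (0.24), and with fry 0 in GMP (0.20) and 0 in LSK (0.35). Some genes are members of several lists.

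Genes were named by a rule fixed before the data were examined. It takes Dnmt3a first and up to 8 genes per direction with the largest called change, KO libraries fully separated from CTRL, a mean of at least 1 CPM and no predicted-gene or clone symbol; where fewer than 4 of a direction pass, the 4 with the smallest p; up to 2 members per list by p (4 where 3 are called); and the 5 with the smallest p per direction for the difference and the mean of effects. To it the 3 most abundant members of lists of other cell types and the sex-linked genes are added. Some genes that this rule takes are not reported here. The edgeR test and camera were tested on simulated counts with known changes, and the other steps were not. For the fit of all 10 libraries, simulated genes without a change had the same mean in GMP and LSK. For a log2 change of 2, edgeR called 69.8% of the simulated genes in GMP, 84.4% in LSK, 44.6% for the difference and 77.3% for the mean. Of the simulated calls, 14 of 142 in GMP and 12 of 162 in LSK were false, above the nominal share of 0.05. A simulated list was recovered at the preset correlation, while with an estimated correlation 0 lists passed in the GMP simulation and 1 in LSK. The simulated genes were drawn independently of each other. These simulations therefore do not test the preset correlation for lists whose genes move together between libraries.

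Alternatives were DESeq2's size factors in edgeR, the deposited size factors, no filter on low counts, at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a fit of all 10 libraries, GMP libraries CTRL-346, CTRL-350 and KO-352 alone, and leaving out each library. Chosen after the data were seen were a sex term (LSK and the joint fits), the share of reads outside genes as a term (GMP), and the lists in GMP libraries CTRL-346, CTRL-350 and KO-352.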

Results

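RNA was sequenced from 2 populations of stem and progenitor cells sorted from mouse bone marrow at 12 months of age. LSK cells (lineage-negative, Sca1+ and cKit+) hold the haematopoietic stem cells and the earliest multipotent progenitors, and GMP (granulocyte-macrophage progenitors, lineage-negative, Sca1−, cKit+, CD34+ and FcgR+) are committed to the myeloid lineage. KO mice carried floxed alleles of Dnmt3a, a de novo DNA methyltransferase, together with the Mx1-Cre transgene, which poly(I:C) induces in blood-forming cells. CTRL mice carried the floxed alleles without Cre, so deletion of Dnmt3a and presence of Cre go together in every comparison. Each population had 3 KO and 2 CTRL libraries, named here by genotype and the number in their title (KO-178). The GMP libraries held 93850256 to 122658636 reads counted on genes and the LSK libraries 29533371 to 30437981. By Xist and Y-linked counts all 5 GMP libraries came from males, whereas LSK libraries CTRL-1326 and KO-1327 came from males and CTRL-1330, KO-1333 and KO-1334 from females.

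Dnmt3a (ENSMUSG00000020661, chromosome 12, 3806007 to 3914443, GRCm38 with GENCODE vM21) was lower in all 6 KO libraries than in any CTRL library of the same population. In LSK it fell from 168 ± 0.87 CPM (SD, n = 2) in CTRL to 62.4 ± 4.05 CPM (n = 3) in KO, a log2 fold change of −1.43 ± 0.08 (SE, edgeR adjusted p = 1.06e-04). In GMP it was 113 ± 19.8 CPM in CTRL and 39.9 ± 20.3 CPM in KO, with 44.7 CPM in KO-178, 57.4 in KO-179 and 17.7 in KO-352. The GMP log2 fold change of −1.50 ± 0.42 did not pass over all genes (edgeR adjusted p = 0.30). These are counts over the whole gene, so they include exons outside the deleted part and do not give the share of cells with a deletion.

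**Figure D1:**
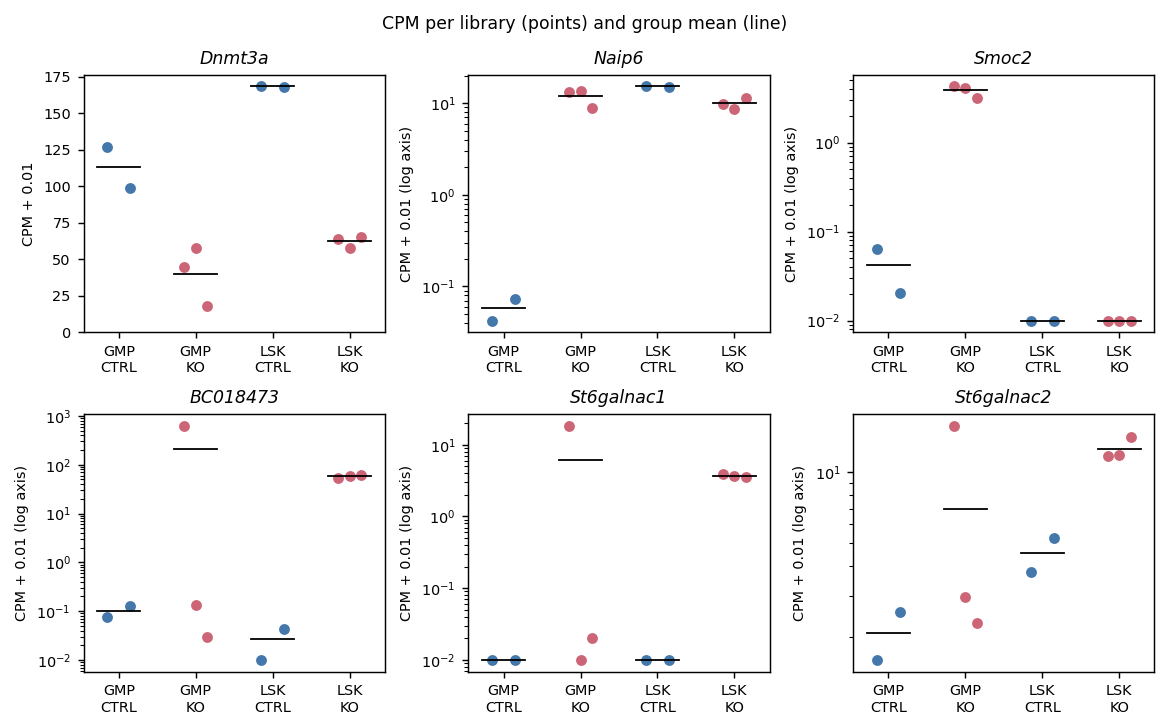
CPM of 6 genes in each library (points) with the group mean (line), for GMP and LSK, CTRL in blue and KO in red; 0.01 CPM was added, and all axes but that of Dnmt3a are logarithmic. Dnmt3a lay lower in all 6 KO libraries, Naip6 was near 0 in GMP CTRL alone, and BC018473 and St6galnac1 were high in all 3 LSK KO libraries and in GMP KO-178.

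The CTRL libraries of the sorted populations were compared first, as a check of the gates. LSK expressed the stem cell genes at higher levels: all 32 tested members of the stem cell and self-renewal list had positive log2 fold changes, 30 of them called, with a median of 3.83 (camera adjusted p = 1.32e-22, adjusted p = 0.089 with an estimated correlation). Lymphoid-primed genes were higher in LSK for 22 of 22 members (median 3.55, camera adjusted p = 2.23e-08, adjusted p = 0.24 with an estimated correlation). Among them were the B-lymphoid adaptor Blnk (4.89 ± 0.35) and the transcription factor Bcl11a (1.63 ± 0.12). The cytokine receptor gene Flt3 was higher by 4.56 ± 0.37. In GMP all 19 tested primary granule genes were higher (median −2.78 for LSK minus GMP, camera adjusted p = 2.37e-31, adjusted p = 0.016 with an estimated correlation). So was the histidine decarboxylase gene Hdc (−4.48 ± 0.10), a mast cell and basophil gene. In total 10442 of 18836 genes passed in edgeR, 5303 higher and 5139 lower in LSK. Of the other lists, those higher in LSK by camera were Hox (median 3.12), erythroid (4.22), megakaryocyte (4.20), B cell (2.47), T and NK cell (3.77), dendritic (1.46), stromal (2.67), interferon (1.66) and cytokine receptor genes (0.65). Lower were secondary granule (−1.96), monocyte (−0.97), mast cell, basophil and eosinophil (−4.24), cell cycle (−0.73), ribosome biogenesis (−0.49) and mitochondrially encoded genes (−15.56). Of these 15 only the mitochondrially encoded list passed with an estimated correlation, and the other adjusted p ran from 0.16 to 0.52. The immediate early (0.18), adhesion (0.37), DNA methylation (−0.36), imprinted (2.02), germline (1.57), p53 (0.27) and sex-linked (−0.91) lists did not pass by camera. With fry, which does not compare a list with other genes, 22 of the 25 lists passed in this comparison. Population coincides here with count table, annotation release and depth. The 13 mitochondrially encoded genes were listed at 0 in all 5 LSK libraries while they took 0.77% to 1.37% of the counts in GMP, so a call can reflect the table as well as the cell. Their median of −15.56 was not set against the floor of 3 counts and is not a measured fold.

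In GMP, few genes differed between KO and CTRL past the threshold, and the clearest were genes almost silent in CTRL. Naip6 (chromosome 13, 100281121 to 100317674), of the NLR family of inflammasome sensors, rose from 0.048 ± 0.021 CPM (SD, n = 2) to 11.8 ± 2.57 CPM (n = 3), a log2 fold change of 7.92 ± 0.42 (SE, edgeR adjusted p = 0.0031). Smoc2, a secreted calcium-binding matrix protein, rose from 0.032 to 3.87 ± 0.61 CPM (log2 fold change 6.87 ± 0.60, adjusted p = 0.041), and Calml4, a calmodulin-like gene, from 0.68 to 8.19 ± 1.93 CPM (3.58 ± 0.32, adjusted p = 0.041). Hdc fell from 409 ± 13.5 to 197 ± 3.39 CPM (−1.05 ± 0.10, adjusted p = 0.041).

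In total 6 genes passed in GMP (4 higher, 2 lower, of 17290 tested). Among them was the processed pseudogene Gm11942, named after its value was seen, with 42.2 ± 7.06 CPM in KO and 0.24 in CTRL. As a pseudogene it can share reads with its parent gene. Naip6 also has near-identical neighbours that can share reads. Of these, looked up after the value of Naip6 was seen, Naip2 (157 CPM in CTRL and 161 in KO) and Naip5 (29.9 and 36.2 CPM) differed by less than the SD of a group. Smoc2, Calml4 and Hdc each lost their call without any 1 of KO-178, KO-179, CTRL-346 and CTRL-350 (adjusted p up to 0.29, 0.34 and 0.62 over all alternatives), and Naip6 without CTRL-350. Of the other genes with the smallest p, the junction protein gene Cgnl1 had a log2 fold change of 3.41 ± 0.35 (adjusted p = 0.065) and the tubulin gene Tuba8 −1.02 ± 0.12 (adjusted p = 0.099). At an unadjusted p under 0.05 there were 2387 genes, against 864.5 for evenly spread p-values. This excess was not compared with other groupings of the libraries, so it does not by itself speak for KO effects. The count of calls rests on the tool and on the libraries: DESeq2 called 719 genes, limma-voom 0, edgeR 172 without KO-352, and 1 to 4 without any other library. The first principal component of GMP (55.1% of variance) separated CTRL-346 and KO-352 from KO-178 and KO-179, which follows the share of reads outside annotated genes (8.5% and 10.3% against 15.5% and 16.1%, and 14.2% in CTRL-350) rather than genotype.

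Genes of mast cells, basophils and eosinophils stood lower as a group in KO GMP. All 19 tested members had negative log2 fold changes, with a median of −1.35, and Hdc passed over all genes while 9 passed lower when adjusted over the list alone (camera adjusted p = 1.34e-16, adjusted p = 0.56 with an estimated correlation). The eosinophil granule gene Prg3 was at 45.1 ± 27.2 CPM in CTRL and 10.7 ± 1.93 in KO (−2.08 ± 0.36, edgeR adjusted p = 0.24). The abundant Prg2 was at 836 ± 578 and 318 ± 69.5 CPM, and Prss34, a basophil protease gene, at 482 ± 471 and 133 ± 47.0 CPM, a spread in CTRL set by library CTRL-350. Relative to the CTRL mean, the list stood at −1.45, −1.05 and −1.23 in KO-178, KO-179 and KO-352, and at −0.63 and 0.63 in CTRL-346 and CTRL-350. B cell genes were also lower on balance, 12 of 14 members with a median of −0.66 (camera adjusted p = 0.0018, adjusted p = 0.56 with an estimated correlation). None passed over all genes and 2 passed adjusted over the list alone. Relative to the CTRL mean, the B cell list stood at −0.30, −0.13 and −0.49 in KO-178, KO-179 and KO-352. It stood at −0.18 and 0.18 in CTRL-346 and CTRL-350, so KO and CTRL overlapped.

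Mature myeloid genes showed the opposite sign in GMP. Of 25 secondary granule and mature neutrophil genes 24 had positive log2 fold changes, with a median of 0.93 (camera adjusted p = 3.51e-04, adjusted p = 0.84 with an estimated correlation), none called over all genes and 1 adjusted over the list alone. Padi4, a histone-citrullinating enzyme of neutrophils, was at 8.44 ± 1.06 CPM in CTRL and 22.2 ± 3.14 in KO (1.39 ± 0.18, edgeR adjusted p = 0.17). This direction depends on the libraries: in libraries CTRL-346, CTRL-350 and KO-352 alone the list was lower in KO (camera adjusted p = 3.89e-04), with the share of reads outside genes as a term it was not called (adjusted p = 0.71), and without CTRL-346 it was not called (adjusted p = 0.30). Monocyte and macrophage genes had a median of 0.25 (camera adjusted p = 0.024, adjusted p = 0.81 with an estimated correlation), with none called over all genes and 4 higher adjusted over the list alone. The call was lost without KO-178 (adjusted p = 0.072), CTRL-346 (0.78) or KO-352 (0.11), and with the share of reads outside genes as a term (0.17). Among them the Fc receptor gene Fcgr1 was at 0.62 ± 0.03 CPM in CTRL and 3.58 ± 0.59 in KO (2.54 ± 0.30, adjusted p = 0.099).

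Further lists passed in GMP at the preset correlation alone. Hoxa and Hoxb genes had a median of 0.36, with 12 of 14 members positive (camera adjusted p = 0.044, adjusted p = 0.84 with an estimated correlation), and Hoxa9 was at 12.9 CPM in CTRL and 22.4 ± 5.92 in KO (0.80 ± 0.24, edgeR adjusted p = 0.31). Lymphoid-primed genes had a median of 0.38 (camera adjusted p = 0.025, adjusted p = 0.81 with an estimated correlation), with none called over all genes and 4 higher and 1 lower adjusted over the list alone. Flt3, a receptor of early progenitors, was at 17.0 CPM in CTRL and 105 ± 44.7 in KO (2.62 ± 0.38, adjusted p = 0.19), and higher in all 3 KO libraries than in both CTRL libraries, a comparison made after its values were seen. The recombinase gene Rag1 was at 0.59 ± 0.54 CPM in CTRL and 0.0099 in KO and did not pass (edgeR adjusted p = 0.24). Primary granule genes were lower with a median of −0.18 (camera adjusted p = 0.019, adjusted p = 0.81 with an estimated correlation), 1 higher and 1 lower adjusted over the list alone. Among them Cebpe, a transcription factor of granulocyte maturation, had −1.21 ± 0.23 (adjusted p = 0.25) and its list mate Gfi1 0.45 ± 0.10 (adjusted p = 0.26). Cell cycle genes were lower for 28 of 35 members with a median of −0.19 (camera adjusted p = 0.0054, adjusted p = 0.56 with an estimated correlation), for example the mitotic kinase gene Plk1 (−0.44 ± 0.11, adjusted p = 0.28). The DNA methylation list, which holds Dnmt3a itself, had a median of −0.15 (camera adjusted p = 0.034, adjusted p = 0.75 with an estimated correlation), and the sex-linked list a median of 0.49 (camera adjusted p = 0.0082, adjusted p = 0.81 with an estimated correlation), 2 higher adjusted over the list alone, with Xist at 0.19 CPM in CTRL and 1.23 ± 0.82 in KO. The Hox call was lost without KO-178 (adjusted p = 0.056), KO-179 (0.12) or CTRL-350 (0.075). The lymphoid-primed, primary granule, DNA methylation and sex-linked calls were lost without CTRL-346 (adjusted p = 0.62, 0.61, 0.18 and 0.095), and these and the Hox call also with the share of reads outside genes as a term (adjusted p 0.060 to 0.19).

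The other 15 lists did not pass in GMP (camera adjusted p from 0.075 to 0.89). Stem cell genes had a median log2 fold change of 0.18 there, erythroid 0.46, megakaryocyte 0.45, T and NK cell 0.85, dendritic and MHC class II −0.45, stromal 0.31, interferon −0.05, and immediate early genes −0.34. Adhesion and homing genes had a median of 0.14, imprinted genes 0.22, germline genes 0.58, p53 targets 0.02, ribosome biogenesis and Myc targets 0.02, cytokine receptor genes 0.04 and mitochondrially encoded genes 0.18. Single members of these lists that led by p did not pass either: the proto-oncogene Myc had 0.66 ± 0.13 (edgeR adjusted p = 0.26), the kinase gene Pim1 1.61 ± 0.31 (adjusted p = 0.25), and the platelet adhesion gene Selp 2.90 ± 0.54 (adjusted p = 0.24).

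In LSK, a pair of neighbouring genes on chromosome 11 was higher and Dnmt3a lower in all 3 KO libraries. BC018473 (ENSMUSG00000056032, an antisense RNA gene at 116752167 to 116759373) was at 53.9, 59.6 and 62.8 CPM in KO-1327, KO-1333 and KO-1334 and had 1 read over both CTRL libraries, a ratio of pooled CPM of 3490 (95% counting interval 626 to 1.38e+05, edgeR adjusted p = 3.37e-07). St6galnac1, a sialyltransferase gene at 116765025 to 116775507, rose from 0 reads in CTRL to 3.67 ± 0.17 CPM (SD, n = 3), at least 72.5-fold higher against a floor of 3 counts over the CTRL group (adjusted p = 0.0017). Its neighbour St6galnac2 was at 4.52 ± 1.05 CPM in CTRL and 12.4 ± 1.32 in KO (1.46 ± 0.19, adjusted p = 0.087), and the pseudogene Gm11735 between them, named after its value was seen, had 0 reads in CTRL and 0.91 ± 0.22 CPM in KO.

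In total 4 genes passed in LSK (2 higher, 2 lower, of 17238 tested). Of the other genes with the smallest p, the collagen chaperone gene Serpinh1 was at 4.62 ± 0.03 CPM in CTRL and 10.8 ± 0.79 in KO (1.22 ± 0.16, edgeR adjusted p = 0.087), the cell cycle inhibitor gene Cdkn2c at 43.5 ± 4.24 and 25.4 ± 1.41 CPM (−0.78 ± 0.11, adjusted p = 0.13) and Scube3 at 18.4 ± 0.52 and 10.1 ± 1.55 CPM (−0.87 ± 0.15, adjusted p = 0.40). DESeq2 called 21 genes, and the joint fit of all 10 libraries called none. The LSK fit had 487 genes under an unadjusted p of 0.05, against 861.9 for evenly spread p-values. Without CTRL-1326 edgeR called 11 and without KO-1333 it called 7. For BC018473 the strand of counting is not given in the sources used here, so reads of antisense partners cannot be told apart.

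In GMP the same chromosome 11 genes, looked up after the LSK values were seen, were high in 1 library. BC018473 was at 636 CPM in GMP KO-178 and at 0.02 to 0.13 CPM in the other 4 GMP libraries. In KO-178, St6galnac1 was at 18.5 CPM, St6galnac2 at 15.7 and Gm11735 at 5.82. In the other KO libraries, KO-179 and KO-352, St6galnac2 was at 2.96 and 2.29 CPM, against 1.60 and 2.56 in CTRL.

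Genes of antigen-presenting cells stood lower as a group in KO LSK. Of 19 dendritic cell and MHC class II genes 18 had negative log2 fold changes, with a median of −0.67 (camera adjusted p = 5.38e-15, adjusted p = 0.24 with an estimated correlation). None passed over all genes and 4 passed lower adjusted over the list alone. Without CTRL-1330 the median was −0.24. H2-Aa had −0.76 ± 0.21 and H2-Eb1 −0.88 ± 0.25 (edgeR adjusted p = 0.9998 for both), and the invariant chain gene Cd74 was at 144 ± 50.4 CPM in CTRL and 89.1 ± 22.6 in KO. Other mature-cell lists were lower too. Monocyte and macrophage genes had a median of −0.26 (camera adjusted p = 1.58e-07, adjusted p = 0.48 with an estimated correlation), with 3 lower adjusted over the list alone, and the call was lost without CTRL-1330 (adjusted p = 0.074). T and NK cell genes had −0.34 (2.76e-06, and adjusted p = 0.24 with an estimated correlation), and mast cell, basophil and eosinophil genes −0.45 in 16 of 17 members negative (2.76e-06, and adjusted p = 0.24 with an estimated correlation). Secondary granule genes had −0.20 (camera adjusted p = 0.0012, adjusted p = 0.66 with an estimated correlation), with 2 lower adjusted over the list alone, and the direction turned without CTRL-1326 (camera adjusted p = 0.021, higher in KO), while the call was lost without KO-1327 (adjusted p = 0.12). B cell genes went the other way, 16 of 17 positive with a median of 0.33 (camera adjusted p = 2.76e-04, adjusted p = 0.64 with an estimated correlation), a call that was lost without KO-1327 (adjusted p = 0.41) or without CTRL-1330 (adjusted p = 0.50).

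Interferon response genes had small negative values in KO LSK, 35 of 36 members with a median of −0.20 (camera adjusted p = 1.54e-08, adjusted p = 0.59 with an estimated correlation), and none passed over all genes or adjusted over the list alone. Ifit1 had −0.65 ± 0.22 and Oas3 −0.48 ± 0.17 (edgeR adjusted p = 0.9998 for both). Against the CTRL mean the list stood at 0.25 in CTRL-1330 and −0.25 in CTRL-1326, and at −0.10, −0.32 and −0.24 in KO-1327, KO-1333 and KO-1334. Without CTRL-1330 it was not called (camera adjusted p = 0.98). Stromal genes had a median of −0.31 (camera adjusted p = 0.0063, adjusted p = 0.47 with an estimated correlation), immediate early genes −0.16 (0.018, and adjusted p = 0.66 with an estimated correlation), and adhesion and homing genes −0.11 (8.49e-04, and adjusted p = 0.24 with an estimated correlation), 2 lower adjusted over the list alone. The stromal call was lost without KO-1327 (adjusted p = 0.36) or CTRL-1330 (0.074), and the immediate early call without CTRL-1326 (0.23), KO-1327 (0.10) or KO-1333 (0.71). Of the adhesion list, the integrin gene Itgb7 had −0.58 ± 0.12 (edgeR adjusted p = 0.72). The DNA methylation list had −0.03 (camera adjusted p = 0.0012, adjusted p = 0.24 with an estimated correlation), with Dnmt3a its called member. The call was lost without CTRL-1326. The list was not tested without Dnmt3a, so its call does not speak for the other members.

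Growth genes had small positive values in KO LSK, and their calls rest on single libraries. All 26 ribosome biogenesis and Myc target genes had positive log2 fold changes, with a median of 0.10 (camera adjusted p = 1.81e-05, adjusted p = 0.65 with an estimated correlation), a call lost without KO-1333 (adjusted p = 0.11). Cell cycle genes were positive for 29 of 35 members with a median of 0.05 (camera adjusted p = 0.0045, adjusted p = 0.66 with an estimated correlation), a call lost without CTRL-1330 (adjusted p = 0.98) or KO-1333 (0.32). The other 11 lists did not pass (camera adjusted p from 0.099 to 0.86): stem cell genes had a median of −0.0031, Hox genes 0.0014, primary granule −0.10, erythroid −0.03, megakaryocyte −0.09, lymphoid-primed 0.09, imprinted 0.06, germline −0.16, p53 targets 0.04, cytokine receptor 0.02 and sex-linked genes −0.31. Among imprinted genes, Dlk1 had 1.55 ± 0.52 and H19 1.59 ± 0.72 (edgeR adjusted p = 0.9998 for both).

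**Figure D2:**
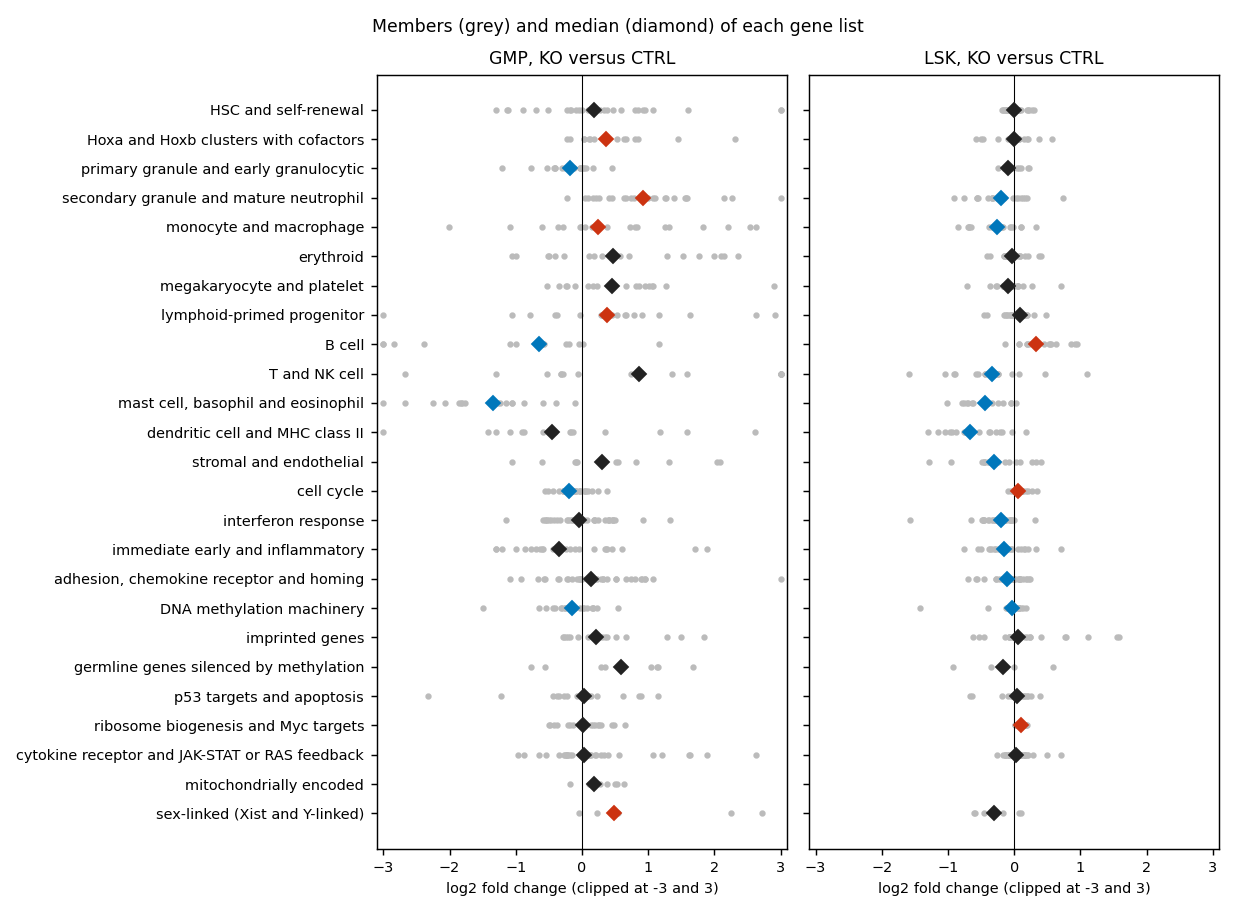
Log2 fold changes, KO versus CTRL, of the tested members of each gene list (grey points, clipped at −3 and 3) and their median (diamond), in GMP (left) and LSK (right); a red or blue diamond marks a list higher or lower in KO by camera with the preset correlation, black marks a list that did not pass. Mast cell, basophil and eosinophil genes had medians of −1.35 in GMP and −0.45 in LSK, and no list passed with an estimated correlation.

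The measured KO effects of the populations showed little correlation across genes. Over 15147 genes tested in both, log2 fold changes had a Pearson r of 0.038 and a Spearman rho of 0.019, and 50.2% had the same sign. These are correlations across genes, which are not independent replicates, and no library is shared between the 2 fits. Noise in the log2 fold changes lowers such a correlation, so a low value does not show that the KO effects differ. In LSK 487 genes had an unadjusted p under 0.05 in edgeR, against 861.9 for evenly spread p-values.

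The effect averaged over both populations passed for 7 of 18836 genes (5 higher, 2 lower). Ephx2, the soluble epoxide hydrolase gene, was higher by 1.61 ± 0.22 on average (adjusted p = 0.048), with 2.55 ± 0.35 in GMP and 0.65 ± 0.25 in LSK. Among the other calls, Naip6 (3.65), Ppp1r9a (0.73), Mcoln2 (0.97), Calml4 (1.64) and Hdc (−0.55) also differed between the populations. Tuba8 (−0.64, adjusted p = 0.061) and Galnt10 (−0.53, adjusted p = 0.073) did not pass. By list, mast cell, basophil and eosinophil genes were lower on average with a median of −0.95 (camera adjusted p = 3.32e-15, adjusted p = 0.36 with an estimated correlation), Hdc called over all genes and 11 adjusted over the list alone. Hox (0.22), secondary granule (0.36) and ribosome biogenesis genes (0.07) were also called higher, and primary granule (−0.12), B cell (−0.35), dendritic (−0.61), interferon (−0.10) and DNA methylation genes (−0.07) lower. With an estimated correlation DNA methylation had adjusted p = 0.44 and the other 7 adjusted p = 0.90. The DNA methylation list holds Dnmt3a and was not tested without it. Medians had opposite signs in GMP and LSK for secondary granule (0.93 and −0.20) and B cell genes (−0.66 and 0.33). The other lists called had the same sign in both, with Hox genes at 0.36 in GMP and 0.0014 in LSK. The count of genes was 4 with a sex term and 473 without GMP KO-352.

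The KO effect differed between the populations for 5 of 18836 genes, each changed in GMP more than in LSK. Naip6 had a log2 fold change of 7.92 in GMP and −0.61 ± 0.15 in LSK (difference −8.54 ± 0.41, edgeR adjusted p = 1.79e-05), and all 5 LSK libraries expressed it at 8.65 to 15.3 CPM. Ppp1r9a, a neurabin gene, had 1.36 in GMP and 0.10 in LSK (difference −1.28 ± 0.13, adjusted p = 0.010), Calml4 3.58 and −0.30 (−3.90 ± 0.43, adjusted p = 0.015), and Mcoln2, a lysosomal channel gene, 1.92 and 0.02 (−1.92 ± 0.23, adjusted p = 0.022). Hdc had −1.05 in GMP and −0.05 in LSK (0.98 ± 0.11, adjusted p = 0.015). Casp12 (−1.43, adjusted p = 0.080), Zfp467 (1.48, adjusted p = 0.14) and Cnn2 (0.63, adjusted p = 0.14) did not pass. The count was 2 with a sex term and 513 without GMP KO-352.

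**Figure D3:**
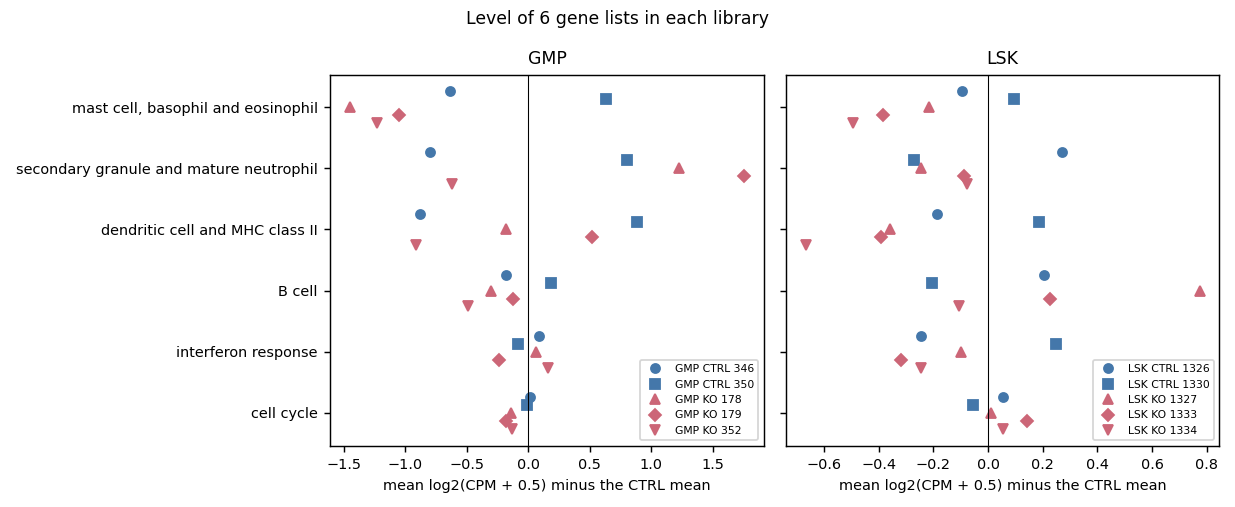
Level of 6 gene lists in each library, as the mean over tested members of log2(CPM + 0.5) minus the mean of the CTRL libraries, for GMP (left) and LSK (right); each point is 1 library, CTRL in blue and KO in red. The mast cell, basophil and eosinophil list lay at −1.45 to −1.05 in the GMP KO libraries, below both CTRL libraries, and the neutrophil list lay at −0.80 and −0.62 in GMP CTRL-346 and KO-352 and at 0.80 to 1.76 in the other 3.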

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

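Of the tests in this part, the spread over the mast cell, basophil and eosinophil genes and the fits with the share of reads outside genes or with a sex term, and the lists in part of the GMP libraries, were chosen after the results were seen. The KO effect differed between the populations, by edgeR's test of the difference itself, for 5 genes. LSK minus GMP, the log2 difference was −8.54 for Naip6, −3.90 for Calml4, −1.92 for Mcoln2, −1.28 for Ppp1r9a and 0.98 for Hdc. No group has more than 3 libraries, so no library was tested as standing apart within its group.

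Whether chance can be excluded for the numbers of calls was asked by regrouping the libraries within each population. The difference of effects gave 5 genes, and 29 of the 100 splits, the real one included, gave as many, up to 870. The mean effect gave 7, and 23 of the 100 splits gave as many, up to 733, so chance is not excluded for either count. Splits that set GMP KO-178, KO-179 and CTRL-350 against CTRL-346 and KO-352 gave 24 to 196 genes for the mean and 23 to 147 for the difference with every grouping of LSK, which points to a structure of the GMP samples other than genotype. The highest counts (733 for the mean, 870 and 567 for the difference) came from GMP CTRL-346, CTRL-350 and KO-352 against KO-178 and KO-179 with single groupings of LSK. With the other LSK groupings that GMP split gave 1 to 15 and 1 to 70. In GMP alone the real split gave 6 calls and the highest other 24 (KO-178, KO-179 and CTRL-350 against CTRL-346 and KO-352, the libraries with the high and the low share of reads outside genes); 3 of 10 splits gave as many. In LSK the real split gave 4, the highest other 10 (females against males), and 4 of 10 splits gave as many; with a sex term LSK gave 4. With 10 splits no share under 0.05 can be reached.

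The lower level of mast cell, basophil and eosinophil genes in KO GMP, to which Hdc belongs, was set against 3 explanations. A trend with the share of reads outside annotated genes is argued against, since with that share as a term the members' median was −1.64, against −1.35 without it. A difference between libraries KO-178 and KO-179 and the rest is left open: the median was −1.49 in libraries CTRL-346, CTRL-350 and KO-352 alone, but there the KO group is 1 library without a spread of its own, and the planned bound did not allow for that. Fewer progenitors of these lineages within the sorted GMP gate also stay open: all 11 members with at least 10 CPM were lower (median −1.27, SD across members 0.589), but from −2.26 to −0.39, which does not decide whether they moved alike. The gate removes lineage-positive cells but, as described in the labels, uses no marker that would separate such progenitors, and loss of Dnmt3a, the presence of Cre and lower transcription per cell remain untested alternatives.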

How the results depend on the processing

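The sex term, the share of reads outside genes as a term and the lists in GMP libraries CTRL-346, CTRL-350 and KO-352 were chosen after the data were seen. Where a value below differs from the one reported, the cause was not tested. No paired analysis was possible because the groups share no replicate numbers. Size factors, deposited or DESeq2's, and a filter of 1 CPM in 2 libraries left the counts of calls within 1.5 times, and with DESeq2's size factors the same 10 GMP and 13 LSK lists passed. With no filter, GMP gave 50 calls (6 without the change), LSK 27 (4), the difference of effects 38 (5) and the mean effect 52 (7). DESeq2 gave 719, 21, 218 and 266 in that order and made all the calls that edgeR made. Limma-voom gave 0 in GMP and 4 in LSK, and in GMP edgeR had 2387 genes at an unadjusted p under 0.05. One fit of all 10 libraries gave 182 in GMP and 0 in LSK, where edgeR had 487 genes at an unadjusted p under 0.05; it pools the spread of both tables. GMP libraries CTRL-346, CTRL-350 and KO-352 alone gave 3, and the share of reads outside genes as a term 182 (61 higher, 121 lower). With a sex term the difference gave 2 and the mean 4.

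Leaving out each library gave 1 to 172 calls in GMP (172 without KO-352, 1 without CTRL-350, 2 without KO-178 or KO-179), 3 to 11 in LSK (11 without CTRL-1326, 7 without KO-1333), 1 to 513 for the difference (513 without GMP KO-352, 15 without GMP KO-179, 1 without GMP CTRL-346, LSK CTRL-1326, CTRL-1330 or KO-1334, 3 without GMP KO-178 or LSK KO-1333) and 3 to 473 for the mean (473 without GMP KO-352, 22 without GMP KO-179, 11 without GMP CTRL-346, 3 without LSK CTRL-1326, 4 without LSK CTRL-1330 or KO-1334). The correlation of effects across genes ranged from −0.0292 to 0.108. Among called genes, Naip6 kept its call in GMP in 12 of 14 alternatives (lost with limma-voom and without CTRL-350), and Smoc2, Calml4 and Hdc in 8. For the difference Naip6 kept it in 14 of 14, Ppp1r9a in 10, Calml4 and Hdc in 7 and Mcoln2 in 5, and for the mean Naip6 and Ppp1r9a in 14, Hdc in 13, Mcoln2 and Ephx2 in 6 and Calml4 in 5. In LSK, Dnmt3a, BC018473 and St6galnac1 kept theirs in 12 of 13, losing it in the fit of all 10 libraries (adjusted p = 1).

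Of the lists, 0 passed in GMP and 0 in LSK with an estimated correlation, and 0 and 0 with fry. In GMP 6 passed with the share of reads outside genes as a term, and 7 to 17 with 1 library left out (17 without CTRL-350), and in LSK 10 to 13. The mast cell, basophil and eosinophil list kept its call in GMP otherwise. Directions turned as follows (camera adjusted p). In GMP libraries CTRL-346, CTRL-350 and KO-352 alone the stem cell list (0.0338), the neutrophil list (3.89e-04), the megakaryocyte list (0.0419) and the adhesion list (0.0419) were lower and the interferon list higher (0.0234). With the share of reads outside genes as a term the neutrophil list had 0.714. Leaving out 1 GMP library, the dendritic list ranged from 1.57e-06 (lower, without CTRL-346) over 0.0212 (higher, without CTRL-350) to 0.884, and the immediate early list from 6.09e-11 (lower, without CTRL-346) over 2.90e-05 (higher, without CTRL-350) to 0.366. In LSK the neutrophil list ranged from 4.74e-13 (lower, without CTRL-1330) over 0.0207 (higher, without CTRL-1326) to 0.119, and the erythroid list from 0.00348 (lower, without CTRL-1326) over 0.0395 (higher, without CTRL-1330) to 0.645. With 1 CTRL library left in a group, its spread is taken from the other group. The lower depth of LSK limits genes under about 1 CPM most.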

Other observations

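In this part the tests on chromosome 11 and the test on mature cells in LSK were chosen after the results were seen, as was the fit with a sex term. Sorted progenitors also held RNA of genes used as markers of mature cells, and some of these varied between libraries. In GMP, Car1, an erythroid carbonic anhydrase gene, was at 5.92 ± 6.36 CPM (SD, n = 2) in CTRL and 30.4 ± 20.2 (n = 3) in KO, the neutrophil gene S100a9 at 551 ± 388 and 947 ± 772 CPM, and the MHC class II gene H2-Ab1 at 34.7 ± 27.6 and 23.06 ± 14.04 CPM. These and the monocyte genes F13a1 (968 ± 104 and 1597 ± 285 CPM) and Ccr2 (180 ± 47.0 and 313 ± 18.9 CPM) did not pass over all genes in edgeR. The monocyte gene Ly6c2 was flat (1132 ± 11.4 and 1122 ± 21.0 CPM). Of the erythroid genes, Tfrc was lower in KO (608 ± 151 and 428 ± 84.5 CPM) and Car2 was at 25.2 ± 4.46 and 28.7 ± 9.60 CPM. In LSK the lymphoid gene Cd79b was at 36.5 ± 4.39 CPM in CTRL and 44.2 ± 4.43 in KO, Car2 at 589 ± 98.2 and 546 ± 31.1, and the platelet gene Plek at 359 ± 10.4 and 279 ± 77.6 CPM.

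Differences between the populations also appeared by list. By the test of the difference (camera on LSK minus GMP), the secondary granule list had a median of −1.14 (adjusted p = 2.72e-05), the B cell list 1.38 (7.13e-08), the mast cell, basophil and eosinophil list 0.98 (8.36e-07) and the cell cycle list 0.21 (1.05e-04). Also called lower were Hox (−0.64), monocyte (−0.62), erythroid (−0.33), megakaryocyte (−0.61), T and NK cell (−0.93) and adhesion genes (−0.26). None of these 10 held with an estimated correlation (adjusted p = 0.77 for each).

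The high values of neighbouring genes on chromosome 11 in LSK KO and in 1 GMP KO library were set against 2 explanations. KO genotype or Cre alone, as a cause that acts alike in every KO library, is argued against. Of the 6 KO libraries 4 had BC018473 above 1 CPM, while GMP KO-179 and KO-352 stayed at the level of CTRL. Within LSK all 3 KO libraries were high and both CTRL libraries were not, so there KO genotype and Cre stay open. A local change at this place stays open and was not decided: 3 of the 11 other tested genes within 200 kb (St6galnac1, St6galnac2 and Gm11735) had an unadjusted p under 0.001 in LSK, against 20 of 17226 elsewhere (one-sided exact hypergeometric test, p = 3.40e-07), which restates what was seen, since the neighbours were known before the window was chosen. What such a change would be, for example a loss of methylation in part of the mice or a difference in their strain background, was not tested, since no methylation or genotype data were analysed here.

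The lower values of interferon genes in KO LSK were set against 2 explanations. A constant shift between the sexes as the whole cause is argued against, since the median was −0.202 with a sex term and −0.203 without it. That term assumes the same KO difference in both sexes, so whether the difference depends on sex is not decided. Against the CTRL mean, the males stood at −0.25 (CTRL-1326) and −0.10 (KO-1327). The females stood at 0.25 (CTRL-1330), −0.32 (KO-1333) and −0.24 (KO-1334). Fewer mature cells carried over in the KO sort stay open: the T and NK, monocyte and dendritic lists were negative, and the B cell list had a median of 0.325 (0.159 to 0.806 when any 1 library was left out), but its level overlapped between KO (0.77, 0.23 and −0.11 against the CTRL mean) and CTRL (0.20 and −0.20). The call rests on CTRL-1330, without which the adjusted p was 0.98, so a higher interferon level in that mouse may account for it. A response that fades at different speed after poly(I:C) was not tested.

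A hypothesis formed from Naip6, Flt3, Mcoln2 and Ppp1r9a, which LSK express at higher levels than GMP CTRL, was that KO GMP keep genes that are high in LSK. Genes at least 3 log2 units higher in LSK CTRL were chosen against 1 GMP CTRL library and compared between KO and the other, so that no CTRL library served both steps. Against CTRL-346 (384 genes chosen against CTRL-350) the median log2 difference was 0.39 for the mean of the KO libraries and 0.04 for KO-352, and against CTRL-350 (509 genes chosen against CTRL-346) it was 0.06 and −0.213. KO-178 had 0.47 and 0.09 and KO-179 0.58 and 0.27 in that order. For genes at least 3 log2 units lower in LSK the mean of the KO libraries had 0.13 and 0.05. The bound set in advance asked for medians above 0 against both CTRL libraries, for the mean of the KO libraries and for KO-352. It was not met, since KO-352 had −0.213 against CTRL-350. That value compares 1 library with 1 other and has no spread. The hypothesis for these genes as a class was therefore neither borne out nor excluded.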
